A study of Homo sapiens with 13 samples.

How the data were processed

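CUT&RUN peak lists from PANC1 cells stably expressing BRG1 were analysed for 12 libraries, 2 replicates each of BRG1, NRF2, SMARCC1, H3K4me1, H3K4me3 and H3K27ac. The labels read PANC1-BRG oe, taken here as BRG1 overexpression. The IgG library was not used here. Groups follow the target and replicate number of the labels. The submitters' processing notes name Bowtie2 2.4.1, SAMtools 1.9, Picard 2.23.9 and MACS2 2.2.7.1 and the GRCh38 build, without stating each tool's role or settings.

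The fold enrichment of each peak is the authors' deposited value, and it was used as binding strength without rescaling. The labels do not state whether peaks were called against the IgG library, so it is not known whether these folds are over IgG or over each library's own background. The −log10 p and −log10 q of each peak, also deposited by the authors, were used only as thresholds in alternatives. The deposited peak score was read but not used in any test. Peaks had been called library by library, and no read counts or coverage were given, so depth is unknown and a missing peak cannot be told from a shallow library. Intervals on shares are exact (Clopper-Pearson) at 95% and cover counting error only.

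From these lists, reproducible sites or regions were computed as merged peaks of both replicates that held at least 1 peak from each. Chromosomes 1 to 22 and X were used. Overlap meant at least 1 bp. A site's strength was the mean over both libraries of its highest fold enrichment, and each library's own share was computed as the spread.

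Shares of factor sites in marks and in other factors were compared with 1000 circular rotations of the sites along each chromosome, one-sided, with a smallest possible p of 0.000999. Marks were compared over the same sites by exact McNemar tests and factors by Fisher's exact test. To compare kinds of acetylated region with each other, a further contrast was made over H3K27ac regions only, by an exact conditional Cochran-Mantel-Haenszel test with 25 strata of region width and of the region's highest fold enrichment. Strength was compared by Spearman and Pearson correlation of log2 fold enrichment with 100000 permutations, and medians with 10000. Adjusted values are Benjamini-Hochberg within each family of tests.

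Gene positions came from the RefSeq annotation of GRCh38.p14, with 19974 protein-coding genes. It gives no strand or exons, so transcription start sites were not known. Sites were assigned to the nearest protein-coding gene span within 50 kb, and the planned promoter share was computed as the share within 1000 bp of either end of a gene. Of 348 symbols on 15 gene lists written in advance, 347 were found. List tests used as background the 9574 genes with an assigned H3K27ac region, here called active, stratified by the number of such regions, with Fisher's exact test beside them. A planned search for 15 sequence motifs was not run, since no genome sequence was at hand.

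Sites named in the text followed a rule: for each factor the 10 sites with the best mean rank of fold enrichment over both libraries, the 5 best ranked sites held by all 3 factors, up to 4 members of each gene list with a site, and 20 genes always looked up. Some genes that the rule names are not reported here. The lists, main tests, most alternatives and this rule were fixed before the data were examined. Thresholds of −log10 p 5 and −log10 q 1.3, thresholds on factor peaks alone, settings for tRNA genes, tests between factors, strength inside against outside marks, distance to tRNA genes, other genes read by RNA polymerase III and shares by chromosome were added after the sites were seen.

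Alternatives were stricter thresholds on peaks, larger overlap, summits, peaks of either replicate, joined mark peaks, equal numbers of mark peaks, other strata, another window around gene ends, each library left out in turn and pairing of same-numbered libraries. With a library left out, every peak of the other replicate of that target counted as a site or region. The rotation test, the stratified odds ratio, the correlation and the gene list test were tried on simulated data, and the other tests were not. Site sets rotated at random gave rotation p under 0.05 in 1% of runs for SMARCC1 in H3K27ac and 2.5% for BRG1, and a planted share of 10% was found in 100% of runs. These sets came from the same rotation as the null, so they check the computation and cannot show that rotation is an apt null. A simulated odds ratio of 3 for BRG1 and H3K4me1 was recovered as 2.99, and its interval held the true value in 95.5% of runs. A simulated correlation of 0.2 between BRG1 and H3K4me1 strength was found in 99.5% of runs, and lists with 10 of 25 genes planted near BRG1 sites in 100%. These last simulations drew values independently, so dependence between neighbouring sites was not covered. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.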

Results

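CUT&RUN releases the DNA beside an antibody-bound protein with a tethered nuclease, so that its reads mark where the protein or the histone modification sits. The series profiled PANC1, an established human pancreatic ductal carcinoma line, here stably expressing BRG1. Every label reads BRG oe, taken here as BRG1 overexpression, and no cells at the line's usual BRG1 level were profiled for comparison. BRG1, encoded by SMARCA4, is a catalytic ATPase of the BAF and PBAF chromatin remodelling complexes, and SMARCC1 is a core subunit of those complexes. NRF2, encoded by NFE2L2, is the transcription factor that switches on antioxidant and detoxification genes. H3K27ac marks active promoters and enhancers, H3K4me3 marks promoters, and H3K4me1 marks enhancers. The labels give 2 replicates for each of these 6 targets, without saying whether they were separate cultures, and an IgG library, which was not used here.

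The BRG1 libraries held 3213 and 6610 peaks, the NRF2 libraries 1538 and 919, and the SMARCC1 libraries 600 and 572. H3K27ac gave 32499 and 32294 peaks, H3K4me1 37283 and 34234, and H3K4me3 18789 and 17752. The peak lists carry no read counts, so the depth of each library is unknown, and the number of peaks limits the precision. The lowest −log10 p of a library lay between 2.01 and 2.04, and the peaks were not filtered on the adjusted value. Only 26 and 57 BRG1 peaks and 170 and 85 NRF2 peaks reached −log10 q of 5, and every SMARCC1 peak had a −log10 q of 0. The share of a library's peaks met by the other replicate was 92.9% ± 0.688 (SD, n = 2) for H3K4me3, 80.5% ± 0.238 (SD, n = 2) for H3K27ac and 69.5% ± 4.84 (SD, n = 2) for H3K4me1. Among the factors it was 47.6% ± 23.5 (SD, n = 2) for BRG1, 35.3% ± 13.8 (SD, n = 2) for NRF2 and 28.9% ± 0.857 (SD, n = 2) for SMARCC1. The 2 values behind each mean are the 2 directions of 1 comparison, such as 64.2% and 31.1% for BRG1. These SDs therefore largely follow how unequal the 2 lists are in length, and do not show how precisely agreement was measured. The reproducible sets, with a peak from both replicates, held 2039 BRG1, 383 NRF2 and 169 SMARCC1 sites, and 24239 H3K27ac, 23538 H3K4me1 and 15638 H3K4me3 regions. The p-values below compare sites, regions or genes with each other, or sites with rotated positions. None measures spread between replicates, and sites, regions and genes are not independent replicates.

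The series title asks how BRG1 binding goes with histone methylation and acetylation. BRG1 sites lay mainly away from promoters: they met H3K27ac and H3K4me1 far more often than H3K4me3. More BRG1 sites lay outside all 3 marks than inside any single mark. Of the 2039 BRG1 sites, 646 met an H3K27ac region, or 31.7% (95% exact binomial interval 29.7 to 33.8), and each library's own peaks gave 29.3% ± 0.826 (SD, n = 2). H3K4me1 was met by 589 BRG1 sites, or 28.9% (26.9 to 30.9), and by 25.9% ± 3.20 (SD, n = 2) of each library's peaks. H3K4me3 was met by 111 BRG1 sites, or 5.44% (4.50 to 6.52), and by 9.27% ± 2.10 (SD, n = 2) of each library's peaks. That last share was 10.8% without BRG1 replicate 1. At −log10 q of at least 5 in all libraries, 8 BRG1 sites remained and 0 of them met a mark. BRG1 sites rotated along their chromosomes met these marks at 0.832%, 0.804% and 0.946%. All 9 shares of factor sites in marks had a one-sided rotation p of 0.000999, adjusted 0.000999, the smallest that 1000 rotations can give. Between marks, 542 BRG1 sites met H3K27ac without H3K4me3 and 7 the reverse (exact McNemar test, two-sided, adjusted p = 2.8e-149 over 9 comparisons). H3K4me1 exceeded H3K4me3 by 585 BRG1 sites to 107 (exact McNemar adjusted p = 5.9e-80), and H3K27ac exceeded H3K4me1 by 376 to 319 (adjusted p = 0.0378).

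**Figure D1:**
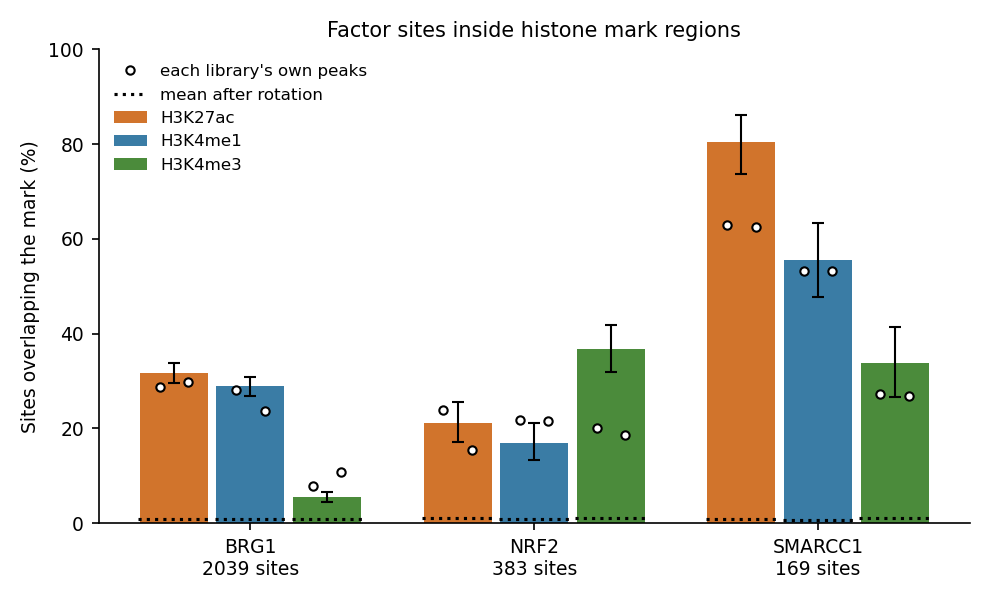
Percent of reproducible BRG1, NRF2 and SMARCC1 sites (horizontal axis groups) that met a region of each histone mark, with exact 95% intervals, points for each library's own peaks and the share of rotated sites. SMARCC1 sites stood at 80.5% in H3K27ac against 31.7% for BRG1.

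By class, 1067 BRG1 sites, or 52.3% (50.1 to 54.5), met none of the 3 marks, with 53.9% ± 0.855 (SD, n = 2) in the libraries. Over 11 other settings this unmarked share ran from 42.5% with peaks of either replicate to 100% for the 8 sites at −log10 q of at least 5. Enhancer-like BRG1 sites, with H3K4me1 and H3K27ac but no H3K4me3, made up 13.0% (11.6 to 14.6), those with H3K4me1 alone 15.6% (14.1 to 17.3) and those with H3K27ac alone 13.5% (12.1 to 15.1). Promoter-like BRG1 sites, with H3K4me3 and H3K27ac, made up 5.10% (4.19 to 6.15), and 9.03% without BRG1 replicate 1. Unmarked and marked BRG1 sites had median fold enrichments of 3.72 and 3.76 (permutation p = 0.343, two-sided).

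Of the 10 BRG1 sites with the best mean rank, 7 met no mark, while the strongest 408 were unmarked at 52.0%, close to the share of all BRG1 sites. The highest, on GRCh38 chromosome 5 from 99900078 to 99900740, had a fold enrichment of 9.59 ± 0.986 (SD, n = 2) and no coding gene within 50 kb, FAM174A being the nearest, and it also held an NRF2 site. The next, on chromosome 2 from 56741741 to 56742011, had 9.40 ± 0.813 (SD, n = 2), again far from its nearest gene CCDC85A. A site 18827 bp from TGFB2, which encodes a secreted growth factor of epithelial-mesenchymal transition, lay in H3K27ac with 7.39 ± 0.440 (SD, n = 2). The site inside LGR4, an R-spondin receptor of Wnt signalling, lay in H3K27ac, and the site 7680 bp from MAN2A1, an enzyme that trims N-glycans, lay in H3K4me1. The unmarked sites also included those near COL17A1, a hemidesmosome collagen, and EEA1, an early endosome tether, and those inside LARP1B, KLF12, a zinc-finger repressor, and WFDC3. The fold enrichments of the 8 sites after the first 2 ran from 6.70 at WFDC3 to 7.67 at KLF12.

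SMARCC1 sites were the most often acetylated of the 3 factors, and enhancer-like and promoter-like regions together held most of them. NRF2 sites stood apart, with H3K4me3 as their most frequent mark. That ranking held only for sites found in both libraries and with the sites near tRNA genes included. Of the 169 SMARCC1 sites, 136 met H3K27ac, or 80.5% (73.7 to 86.2), with 62.7% ± 0.174 (SD, n = 2) in the libraries. Enhancer-like SMARCC1 sites made up 41.4% (33.9 to 49.2) and promoter-like ones 32.5% (25.5 to 40.2). H3K4me1 was met by 55.6% (47.8 to 63.2) and H3K4me3 by 33.7% (26.6 to 41.4) of SMARCC1 sites, with 53.2% ± 0.0140 (SD, n = 2) and 27.1% ± 0.290 (SD, n = 2) in the libraries. SMARCC1 met H3K27ac without H3K4me1 at 57 sites and the reverse at 15 (exact McNemar adjusted p = 1.2e-06). BRG1 sites met H3K27ac less often than SMARCC1 sites (Fisher's exact test, odds ratio 0.113, adjusted p = 2.3e-35), and H3K4me3 less often too (odds ratio 0.113, adjusted p = 2.2e-25). Unmarked SMARCC1 sites were 9.47% (5.51 to 14.9), and 17.5% without SMARCC1 replicate 1 and 17.3% without SMARCC1 replicate 2.

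Among SMARCC1 sites, those with the best mean ranks lay inside or beside NDUFAF6, a complex I assembly factor, RSF1, a subunit of an ISWI remodeller, ABCC1, a glutathione-conjugate exporter, and EXOC7, part of the exocyst. The NDUFAF6 site, on chromosome 8 from 95024532 to 95024894, had a fold enrichment of 4.70 ± 0.390 (SD, n = 2) and met H3K4me3 and H3K27ac. The RSF1 site, on chromosome 11 from 77705523 to 77705805, had 4.58 ± 0.247 (SD, n = 2), met H3K4me1 and H3K27ac, and held a BRG1 site. The ABCC1 site reached 4.28 ± 0.153 (SD, n = 2) in H3K4me1 and H3K27ac. The remaining SMARCC1 sites of the 10 lay at or near LPIN3, ZNF619, BCAS3, NLRP3, the inflammasome sensor, OSBPL9 and BRSK1, with fold enrichments from 3.95 at OSBPL9 to 4.42 at BCAS3. Only the NLRP3 site among these 10 was unmarked.

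NRF2 sites met H3K4me3 in 141 of 383 cases, or 36.8% (32.0 to 41.9), H3K27ac in 21.1% (17.2 to 25.6) and H3K4me1 in 17% (13.3 to 21.1). The libraries' own peaks gave 19.3% ± 1.17 (SD, n = 2), 19.7% ± 5.95 (SD, n = 2) and 21.7% ± 0.0902 (SD, n = 2). The H3K4me3 share was 18.5% without NRF2 replicate 1 and 20.2% without NRF2 replicate 2, so H3K4me3 led only among sites found in both libraries. NRF2 sites in H3K4me3 without H3K27ac made up 32.1% (27.5 to 37.0), but 14.9% without NRF2 replicate 1 and 13.3% without NRF2 replicate 2, and unmarked ones 41.0% (36.0 to 46.1). Of the NRF2 sites, 205, or 53.5% (48.4 to 58.6), lay within 1000 bp of a tRNA gene, a fact looked up after the sites were seen; without NRF2 replicate 1 or 2 the shares were 26.3% and 21.1%. The other 178 NRF2 sites met H3K27ac at 40.4%, H3K4me1 at 36.5% and H3K4me3 at 10.7%.

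All 10 leading NRF2 sites lay at tRNA genes. The first, on chromosome 11 from 59550732 to 59551725, had a fold enrichment of 21.9 ± 1.71 (SD, n = 2), met no mark, and lay 22672 bp from OSBP, a sterol-binding protein gene. The second, on chromosome 6 from 28981305 to 28982165, had 14.7 ± 3.04 (SD, n = 2), and the third, inside SHF on chromosome 15, had 14.9 ± 2.18 (SD, n = 2). Those and the sites whose nearest coding genes were CFAP418, WNT11, BORCS6, HSPA6, TRIM27, OR2B2 and MORF4L1 met H3K4me3 without H3K27ac, and ZNF311 was the nearest coding gene of the second. The coding genes serve only to place these sites, since each lay within 1000 bp of a tRNA gene.

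**Figure D2:**
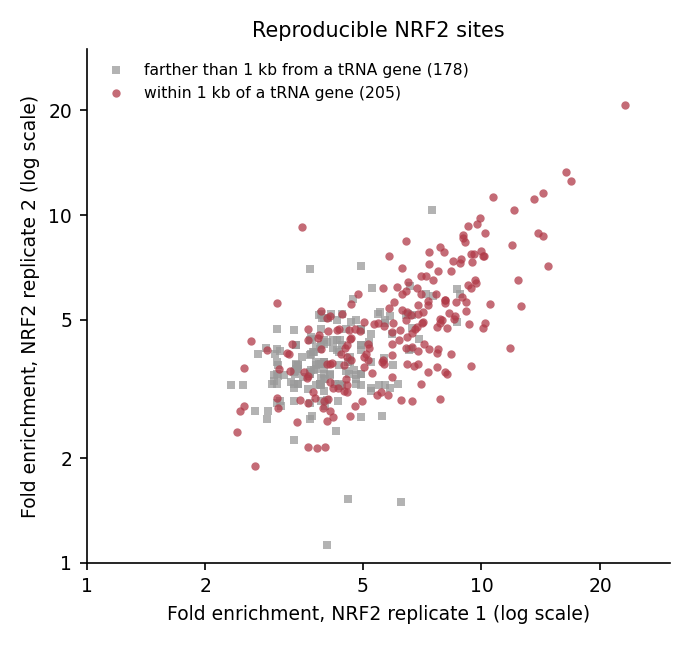
Fold enrichment of each of the 383 reproducible NRF2 sites in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), with the 205 sites within 1000 bp of a tRNA gene marked. The strongest sites in both libraries were near tRNA genes, whose median fold enrichment was 5.43 against 3.88 for the other 178.

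Within acetylated chromatin, all 3 factors preferred enhancer-like over promoter-like regions. Of the 24239 H3K27ac regions, those with BRG1 carried H3K4me1 at 47.1% against 20.1% of those without, and H3K4me3 at 16.2% against 55.9%. With region width and height held in 25 strata, the odds ratio of BRG1 was 3.60 (95% interval 3.08 to 4.21, exact conditional test, two-sided, adjusted p = 1.7e-53 over 6 tests) for H3K4me1 and 0.112 (0.0892 to 0.141, adjusted p = 1.4e-111) for H3K4me3. The latter was 0.247 without BRG1 replicate 1 and 0.175 without BRG1 replicate 2. For SMARCC1 the odds ratios by the same exact test were 6.33 (4.44 to 9.03, adjusted p = 2.9e-24) for H3K4me1 and 0.322 (0.221 to 0.470, adjusted p = 9.0e-09) for H3K4me3. For NRF2 they were, again by the exact test, 4.71 (3.04 to 7.28, adjusted p = 1.7e-11) and 0.241 (0.143 to 0.405, adjusted p = 3.6e-09). With the sites near tRNA genes left out, the NRF2 odds ratios were 6.33 for H3K4me1 and 0.127 for H3K4me3. At peaks with −log10 q of at least 1.3 the NRF2 odds ratio for H3K4me3 was 0.998. Each NRF2 odds ratio kept its call in 8 of 10 other settings. Neither was past the threshold at that setting or at −log10 p of at least 5.

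**Figure D3:**
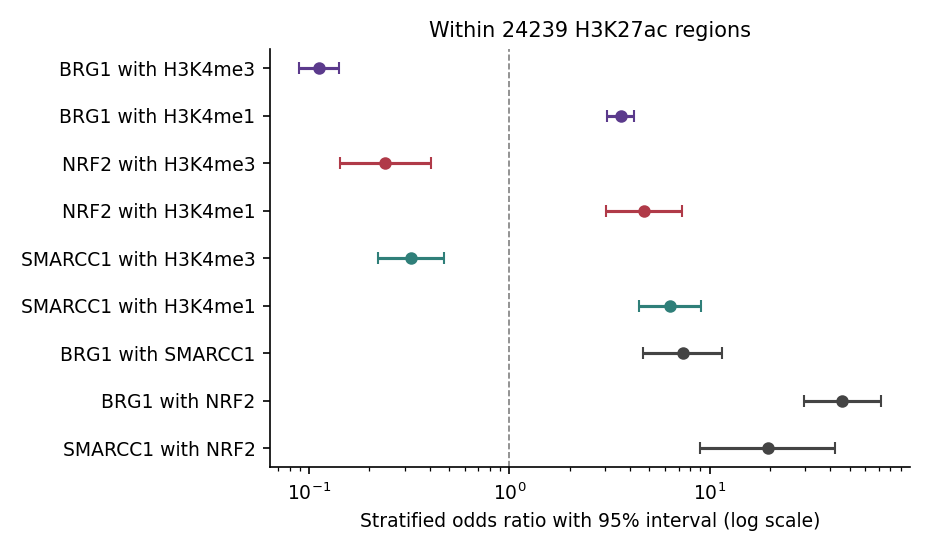
Stratified odds ratios (log axis) over H3K27ac regions, with 95% intervals, of BRG1, NRF2 and SMARCC1 with H3K4me3 and H3K4me1 and of the 3 factors with each other. The 3 H3K4me1 values lay between 3.60 and 6.33, and the 3 H3K4me3 values between 0.112 and 0.322.

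Each mark was most frequent at the summits of the factor sites. H3K27ac covered 26.3% of BRG1 summits and 8.68% of positions 1000 bp away, and 80.5% of SMARCC1 summits and 14.2% of positions 1000 bp away. H3K4me3 covered 29.0% of NRF2 summits and 15.3% of positions 1000 bp away, but did not fall evenly. On the side of lower coordinates it covered 17.2% at 200 bp and 20.9% at 500 bp. On the other side it covered 21.1% at 300 bp and 24.5% at 500 bp.

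**Figure D4:**
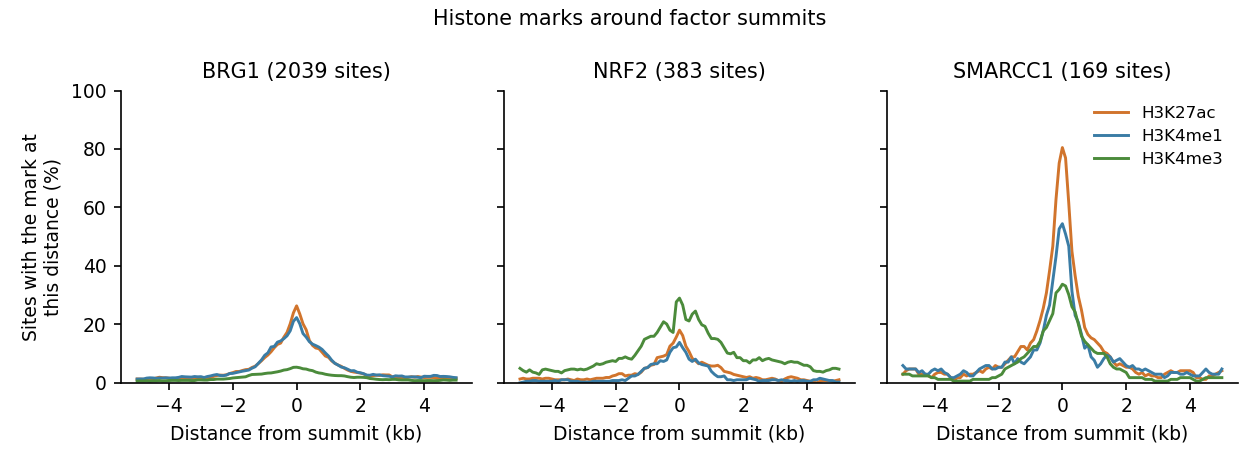
Percent of BRG1, NRF2 and SMARCC1 sites covered by a region of each mark (vertical axis) by distance from the summit in kb. Every curve was highest at the summit, as for SMARCC1 and H3K27ac at 80.5%.

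The factors shared sites far beyond rotated position. Rotation runs along whole chromosomes, so it cannot tell binding together from shared open chromatin or a background common to these libraries. No test here separated these for BRG1 and NRF2. BRG1 and SMARCC1, partners in the same complexes, met at a minority of SMARCC1 sites. SMARCC1 replicate 1 peaks met SMARCC1 replicate 2 peaks at only 28.3%, and the longer list of BRG1 replicate 2 peaks at 25.3%. With agreement this low, the minority cannot show that BRG1 and SMARCC1 bind apart. BRG1 held 15.4% of the SMARCC1 sites, against 0.0533% after rotation, and 32.5% without BRG1 replicate 1, where it held 32.4% of the NRF2 sites. The odds ratio for both in an H3K27ac region was 7.33 (4.67 to 11.5, exact conditional test, two-sided, adjusted p = 1.4e-12 over 3 pairs). BRG1 held 24.3% of the NRF2 sites, against 0.0856% after rotation, with an odds ratio of 45.9 (29.4 to 71.5, exact conditional test, adjusted p = 1.2e-48), which was 26.3 without BRG1 replicate 1 and 26.1 without NRF2 replicate 2. Over the other settings it ran from 22.1 with peaks of either replicate to 129 at −log10 p of at least 5. At −log10 q of at least 1.3, BRG1 held 3.40% of 147 NRF2 sites. NRF2 held 4.73% of the SMARCC1 sites, against 0.0130% after rotation, and 11.8% without NRF2 replicate 2. That pair's odds ratio was 19.5 (8.96 to 42.5, exact conditional test, adjusted p = 3.0e-08), and 9.65 without NRF2 replicate 2 and 11.1 without SMARCC1 replicate 2. All 3 shares had a rotation p of 0.000999, the smallest possible. NRF2 replicate 1 peaks met BRG1 replicate 2 peaks at 36.9% and NRF2 replicate 2 peaks at 25.5%, lists of 6610 and 919 peaks, and a longer list has more chances to be met. The order turned for NRF2 replicate 2 peaks, which met BRG1 replicate 2 peaks at 32.4% and the 1538 NRF2 replicate 1 peaks at 45.0%. None of the 205 NRF2 sites near tRNA genes held a BRG1 site, which allows a share of up to 1.78%, and 93 of the other 178 did.

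All 3 factors met at 8 BRG1 sites, each in H3K27ac. The best ranked, inside ZFAND1, a stress granule factor, on chromosome 8 from 81721225 to 81721639, had a BRG1 fold enrichment of 5.52 ± 1.83 (SD, n = 2) and also met H3K4me3. The IQGAP1 site, inside a cytoskeletal scaffold gene on chromosome 15 from 90400781 to 90401214, had 5.62 ± 0.698 (SD, n = 2). Sites near MTURN, ATIC, a purine synthesis enzyme, and KLHL41 carried H3K4me1 and H3K27ac, with BRG1 fold enrichments of 4.80 ± 0.0397 (SD, n = 2), 4.61 ± 0.894 (SD, n = 2) and 4.47 ± 0.133 (SD, n = 2).

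Inside a mark, stronger BRG1 sites hardly went with stronger marks. Across the 646 BRG1 sites in H3K27ac, Spearman's rho was 0.0622 (permutation p = 0.114, two-sided, adjusted 0.171 over 3 marks) and Pearson's r 0.0544 (p = 0.167, adjusted 0.250). Without BRG1 replicate 1 rho was 0.0719 and without H3K27ac replicate 2 it was 0.0922, both past the threshold, and the lowest rho with 1 library left out was 0.0118. With a library left out, all peaks of the other replicate count, so these values rest on sets other than the 646 sites. For sites outside H3K4me3, rho was 0.0944 with H3K27ac and 0.0827 with H3K4me1, both past the threshold. There the adjustment ran over H3K27ac and H3K4me1 only, since no such site meets H3K4me3, so it was milder. Across 589 BRG1 sites in H3K4me1, rho was 0.0814 (p = 0.0491, adjusted 0.147) and r 0.0926 (p = 0.0244, adjusted 0.0731); rho was 0.0484 without BRG1 replicate 1 and 0.0511 without H3K4me1 replicate 1. Across 111 in H3K4me3, rho was 0.0172 (p = 0.858, adjusted 0.858) and r 0.0457 (p = 0.633, adjusted 0.633), with rho from −0.0413 without H3K4me3 replicate 2 to 0.0786 without BRG1 replicate 2. Leaving out the 2 sites farthest from the BRG1 median gave r of 0.0594, 0.0835 and 0.0418. These relations run across sites, which are not independent.

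BRG1 sites were rare at gene ends, and SMARCC1 sites were not. Of BRG1 sites 4.81% lay within 1000 bp of an end of a coding gene, with 7.14% ± 1.39 (SD, n = 2) in the libraries, against 2.74% after rotation. The share was 8.12% without BRG1 replicate 1. SMARCC1 gave 27.8% against 3.46%, and NRF2 12.5% against 3.16% (7.62% without NRF2 replicate 1, 7.30% with the sites near tRNA genes left out and 26.3% at −log10 q of at least 5). Each of these 3 had a one-sided rotation p of 0.000999. H3K4me3 regions gave 75.2%, H3K27ac 43.3% and H3K4me1 5.46%. At 5000 bp, the BRG1 share of 10.8% was no longer past the threshold (permutation by rotation, p = 0.188).

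Gene lists asked whether factor sites gathered near genes of pancreatic cancer states or of known NRF2 and BRG1 biology. None of 45 tests, of 15 lists by 3 factors, passed an adjusted 0.05 by the exact conditional test; 1 passed at unadjusted p under 0.05, and Fisher's exact test gave 0 and 1. That 1 was the basal-like pancreatic cancer list, with a BRG1 site near 4 of 7 active genes, or 57.1% against 9.70% of other active genes (odds ratio 8.34, 1.61 to 43.2, exact conditional p = 0.00522, adjusted 0.235). Its genes with a BRG1 site, active or not, included SLC2A1, the main glucose transporter, FGFBP1, a carrier of fibroblast growth factors, and AREG, an EGFR ligand. AREG had an unmarked site inside the gene, and SLC2A1 had its site in H3K4me3 and H3K27ac.

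For mesenchymal genes, BRG1 sites lay near 4 of 22 active genes, TGFB2, TGFBI, AXL, a receptor kinase, and ITGB1, an integrin subunit, with a stratified odds ratio of 1.12 (0.357 to 3.50). YAP and TEAD targets gave 4 of 19, TGFB2 with MYOF, PTPN14 and AMOTL1, and an odds ratio of 0.988 (0.313 to 3.12). Hypoxia and glycolysis gave 4 of 17, SLC2A1 with PFKFB3, LDHA, which makes lactate, and VEGFA, the angiogenic factor, and an odds ratio of 1.42 (0.431 to 4.70). None of these 3 passed the threshold when genes with similar numbers of H3K27ac regions were compared. They did not pass without strata either (Fisher's exact test, unadjusted p = 0.160, 0.106 and 0.0762). The AP-1 family, active or not, had BRG1 sites inside BATF and 16145 bp from JUN, classical pancreatic cancer at AGR2, BAF and PBAF subunits at ARID1B, and ribosomal proteins at RPS3. SMARCC1 sites lay at ABCC1 of the NRF2 targets, CCNB1 of the cell cycle list, RPL11 of the ribosomal proteins and BCL7C of the BAF and PBAF subunits. For pancreatic duct, acinar and endocrine genes, blood cells and hepatocytes, 0 active genes had a site of any factor, and the numbers of active genes were 11, 3, 1, 2 and 1.

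NRF2 sites lay near 1 of 28 active NRF2 targets, or 3.57% against 1.44% of other active genes (odds ratio 2.14, 0.279 to 16.5). That gene was ABCC2, an exporter of conjugated drugs, with the site 2440 bp away. It lay in H3K27ac and met BRG1 sites on chromosome 10, from 99779742 to 99780199, with a fold enrichment of 3.67 ± 0.374 (SD, n = 2). BRG1 sites lay near ABCC2 and inside SLC7A11, the cystine importer, and ABCC3. Of the 28 active targets, 2 had a BRG1 site near them, or 7.14% against 9.74% (odds ratio 0.403, 0.0859 to 1.89). NQO1, HMOX1, GCLM, GCLC, TXNRD1 and SRXN1, antioxidant genes that NRF2 switches on, had no site of any factor assigned. TXNRD1 did hold 3 BRG1 peaks, counted over both libraries, but none formed a reproducible site. NFE2L2 itself had a BRG1 site 132 bp away.

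Of the genes named in advance, SMARCA4 and SMARCC1 had no site of the 3 factors, and no factor library had a peak inside SMARCA4. VIM, a mesenchymal filament gene, KRT19, a ductal keratin gene, SOX9, GATA6, FOSL1, CCN1, CCN2 and MYC likewise had none assigned, though SOX9 held 1 BRG1 peak of a single library. CDH1, the epithelial cadherin gene, also had none assigned, and its nearest BRG1 site was 4880 bp away.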

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

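The comparisons of factors over H3K27ac regions were planned as separate tests for each factor; the tests between factors, and the test on the strongest BRG1 sites, were chosen only after the results were seen.

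BRG1 and SMARCC1 belong to the same complexes and shared H3K27ac regions beyond chance (odds ratio 7.33), but the regions holding only one of them differed in their other marks. Of 750 H3K27ac regions holding 1 of the 2 but not both, those with BRG1 carried H3K4me3 in 15.9% of cases and those with SMARCC1 in 44.0%, an odds ratio of 0.348 (0.213 to 0.570, exact conditional test, adjusted p = 2.6e-04 over 6 tests). It was 0.633 without BRG1 replicate 1 and 0.624 without BRG1 replicate 2, neither past the threshold, so the H3K4me3 difference rests on BRG1 sites found in both libraries. H3K4me1 was also less frequent with BRG1, at 46.5% against 60.6%, an odds ratio of 0.555 (0.361 to 0.854, exact adjusted p = 0.0132). BRG1 and NRF2 differed over 658 such regions, of which only 38 held NRF2, with H3K4me3 at 16.6% against 39.5%, an odds ratio of 0.237 (0.115 to 0.487, exact adjusted p = 3.1e-04). With the NRF2 sites near tRNA genes left out, 28 regions held NRF2 alone and the odds ratio was 0.511 (0.204 to 1.28, exact p = 0.159), so this difference depends on the sites at tRNA genes. Each was singled out because the factors' marks differed by a test of the difference itself. For BRG1 against NRF2, H3K4me1 did not differ detectably (odds ratio 1.04, 0.524 to 2.08, exact adjusted p = 1), and neither mark separated SMARCC1 from NRF2 (1.41 and 1.75, adjusted p = 0.499 and 0.174).

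The wider pattern was that BRG1 sites were less often acetylated than SMARCC1 sites, at 31.7% against 80.5%. More and weaker BRG1 calls were argued against, since the 169 strongest BRG1 sites met H3K27ac at 30.2% (23.4 to 37.7), far under the lower bound of 73.7% for SMARCC1. The scarcity of BRG1 sites on chromosomes 16, 17, 19 and 22 was argued against too, since off these chromosomes the shares were 31.2% (29.2 to 33.3) and 79.3% (71.6 to 85.7). Background of open chromatin in the SMARCC1 libraries cannot be told apart from binding: SMARCC1 replicate 1 peaks met NRF2 replicate 1 peaks at only 7.5% against 28.3% for SMARCC1 replicate 2, but met the longer list of BRG1 replicate 2 peaks at 25.3% (21.9 to 29.0). A background particular to the SMARCC1 libraries need not appear in NRF2 libraries, so a bound set on NRF2 alone was too narrow. No biological explanation was tested, since the design holds 1 cell line, labelled as overexpressing BRG1, and no BRG1-free control.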

How the results depend on the processing

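The thresholds of −log10 p 5 and −log10 q 1.3, those on factor peaks alone, the settings for tRNA genes, and those for tests between factors were chosen after seeing the data. Of 350 combinations of a tested main result with another setting, 325 kept direction and side of the threshold, 10 were weaker, 4 stronger and 11 counted as reversed. Those 11 were values of 0 at strict thresholds, where few sites or mark regions were left. They are lost overlaps and do not show an effect in the other direction. Of the 122 combinations that left out 1 library, 120 kept both and 2 were stronger. Leaving out a library counted every peak of the other replicate, such as 6610 BRG1 peaks in place of 2039 reproducible sites. With more sites a call is harder to lose, so these kept calls are weak evidence of stability. Class shares, which carry no test, held less well: of 275 combinations for marked classes, 125 moved by less than the spread between replicates and 150 by more. The odds ratios of BRG1 kept both in all settings run, from 0.0117 to 0.247 for H3K4me3 and from 2.44 to 5.31 for H3K4me1. SMARCC1 in H3K27ac stayed between 58.6% and 100% (the latter with 3 sites), NRF2 near tRNA genes between 50.9% and 90.8% with both NRF2 libraries and 21.1% to 26.3% with 1, and no gene list passed in any of 8 other settings.

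Strict thresholds left few sites. At −log10 q of at least 5, 8 BRG1, 76 NRF2 and 0 SMARCC1 sites and 1579 H3K27ac, 54 H3K4me1 and 11979 H3K4me3 regions remained. There BRG1 gave 0% in H3K27ac, 0% in H3K4me1, 0% in H3K4me3 and 0% at gene ends, NRF2 gave 0% in H3K27ac and 0% in H3K4me1, and 100% of BRG1 and 51.3% of NRF2 sites were unmarked. With that threshold on factor peaks alone, BRG1 gave 0% in H3K4me1 and 0% in H3K4me3, NRF2 5.26% in H3K27ac and 1.32% in H3K4me1, and 75.0% of BRG1 and 32.9% of NRF2 sites were unmarked.

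At −log10 p of at least 5, 373 BRG1, 191 NRF2 and 3 SMARCC1 sites remained. NRF2 odds ratios were 0.220 for H3K4me3 and 3.89 for H3K4me1, and SMARCC1 gave 0.172 for H3K4me3, none of them past the threshold. SMARCC1 sites with BRG1 came to 0%, with an odds ratio of 0, and those with NRF2 to 0%. Unmarked were 81.5% of BRG1, 46.1% of NRF2 and 0% of SMARCC1 sites, and with the threshold on factor peaks alone 60.1%, 35.6% and 0%. At −log10 q of at least 1.3, with 174 BRG1 and 147 NRF2 sites, BRG1 gave 1.15% in H3K4me3 and NRF2 0.680% in H3K4me1. The NRF2 odds ratios were 0.998 for H3K4me3 and 3.71 for H3K4me1, neither past the threshold, and 79.3% of BRG1 sites were unmarked. Fewer sites and mark regions were left at these thresholds, and the cause of the lost calls was not tested.

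The unmarked shares moved with how marks were counted, for BRG1, NRF2 and SMARCC1 as given. An overlap of at least 50% of a site gave 59.7% and 51.2% for BRG1 and NRF2, and summits inside the mark 60.6% and 51.2%. Peaks of either replicate gave 42.5% for BRG1 and 12.3% for SMARCC1. Mark peaks joined within 1000 bp gave 45.5% and 33.4% for BRG1 and NRF2, and equal numbers of mark peaks 69.4%, 48.3% and 14.8%. Leaving out 1 library gave 48.7% to 54.5% for BRG1, 36.8% to 55.6% for NRF2 and 7.69% to 17.5% for SMARCC1.

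Within 5000 bp of a gene end BRG1 came to 10.8%, no longer past the threshold, and the cause was not tested. Outside H3K4me3, rho of BRG1 strength was 0.0944 with H3K27ac and 0.0827 with H3K4me1, both past the threshold. The adjustment then ran over H3K27ac and H3K4me1 only, since no such site meets H3K4me3. Over all sites, rho with H3K4me1 was already 0.0814, at an unadjusted permutation p of 0.0491. Leaving out 1 library gave rho with H3K27ac from 0.0118 to 0.0922. The cause of these changes in rho with H3K27ac was not tested.

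The replicate block, with same-numbered libraries paired, gave unmarked shares of 49.1% for BRG1, 48.8% for NRF2 and 13.9% for SMARCC1, and changed no call. Same-numbered mark libraries did not deviate together, with correlations of −0.0457, 0.0112 and −0.0178, so the numbers gave no sign of pairing among the mark libraries; factor libraries were not included in this check.

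SMARCC1 could not be tested at either −log10 q threshold, nor odds ratios at 5, since none or too few sites were left. Motifs were not run. Depth is unknown, so a share of 0 at a strict threshold does not show that a mark is absent.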

Other observations

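The looks at tRNA genes, polymerase III genes and chromosomes were all chosen only after the sites were seen, as were the tests of the chromosome 6 cluster and of antibody cross-reaction.

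tRNA genes are short genes read by RNA polymerase III, clustered mainly on chromosomes 6 and 1. NRF2 sites gathered at them: 218 of 443 tRNA genes, or 49.2% (44.5 to 54.0), had an NRF2 site within 1000 bp, and 47 of the 50 best ranked NRF2 sites lay there. Of tRNA genes on chromosome 6, 95 of 155 had one, on chromosome 17 29 of 33, on chromosome 1 19 of 98, and on chromosome 7 1 of 22. H3K4me3 lay within 1000 bp of 170 of the 218 tRNA genes with an NRF2 site and of 47 of the other 225 (Fisher's exact test, odds ratio 13.4, adjusted p = 2.1e-34 over 3 marks), while H3K27ac did not differ detectably, at 24 and 18 (p = 0.331). Other polymerase III genes with an NRF2 site were VTRNA1-1 and VTRNA1-2, which encode vault RNAs, RNY1, RNY3 and RNY4, which encode Y RNAs, and RMRP, the RNA of RNase MRP, 6 of 16 looked up; none of the 16 had a BRG1 or SMARCC1 site.

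A background shared by all libraries was argued against, since 0 of the 218 tRNA genes with an NRF2 site, with an upper bound of 1.68%, held a BRG1 or SMARCC1 peak in any library. Extra copies of the chromosome 6 cluster were argued against as the whole cause, since off that chromosome 41.1% (35.1 to 47.3) of NRF2 sites still lay near a tRNA gene, against at most 3.04% after rotation. An antibody that binds another protein at tRNA genes cannot be told apart from NRF2 itself: away from tRNA genes the NRF2 target list gave an exact p of 0.327, with 1 gene, which decides nothing. A background particular to the NRF2 libraries stays open as well, since use of IgG in peak calling is not stated, and no biological explanation was tested.

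BRG1 sites outside the 3 marks were the largest BRG1 class in all 5 equal groups of BRG1 strength, from 49.5% in the middle group to 57.0% in the weakest. Sites in gaps beside mark regions were argued against as the whole cause, since 33.5% (30.6 to 36.4) of the 1067 lay within 1000 bp of a mark, although rotated sites did so at 4.09%, and so were mark peaks found in 1 library only, since 40.5% (38.4 to 42.7) of BRG1 sites lay outside mark peaks of either library. Chance calls were argued against for these reproducible sites, since 65.0% (62.7 to 67.3) of unmarked BRG1 replicate 1 peaks met a replicate 2 peak, close to the 63.4% of marked ones and against at most 0.467% after rotation. In the other direction 31.1% of the 6610 replicate 2 peaks met the shorter list of 3213, against 0.0738% after rotation, so most replicate 2 peaks were not found again. A recurring background in the BRG1 libraries stays open, as do base composition and repeats, for which no genome sequence was at hand, and no biological explanation was tested.

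Sites that BRG1 shared with SMARCC1 were all marked: 0 of 26 were unmarked, against 53.0% of the other BRG1 sites (Fisher's exact test, adjusted p = 8.3e-09). SMARCC1 sites as a whole were unmarked at only 9.47%, or 16 of 169, so this contrast largely restates that SMARCC1 sites lie in marks. Of the 94 BRG1 sites shared with NRF2, 36 were unmarked (odds ratio 0.557, 0.362 to 0.857, Fisher's exact p = 0.00739), or 38.3%, near the 41.0% of all NRF2 sites. On the gene-rich chromosomes 16, 17, 19 and 22, which hold 19.7% of coding genes, lay 3.92% (3.12 to 4.86) of BRG1 sites, 17.2% (11.8 to 23.7) of SMARCC1 sites and 13.9% of H3K27ac regions without H3K4me3. BRG1 differed there from SMARCC1 (odds ratio 0.197, Fisher's exact p = 5.0e-10) and from H3K4me1 regions, at 7.60% (odds ratio 0.496, adjusted p = 8.2e-11).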
